A study of Mus musculus with 12 samples.

How the data were processed

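Thymocytes at the DN2, DN3 and DN4 stages were profiled in 4 sorts each, on 12 Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols, thymocytes of 4 mice per sort were depleted of CD4+ and CD8+ cells on magnetic columns, stained for CD44 with FITC and CD25 with PerCP-Cy5.5, and sorted as negative for lineage markers stained with PE. RNA was purified on RNeasy Mini columns and amplified in a protocol of repeated cDNA synthesis, per the labels. The deposited intensity values are linear probe set signals made with Affymetrix GCOS, per the submitters' processing notes; its version, algorithm and scaling target are not given in the sources used here. Groups and sort numbers were taken from the sample labels.

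The table held 45101 probe sets, of which 64 were control probe sets. In the platform annotation 34958 probe sets had 1 gene symbol, 932 had several and 9211 were not listed with a gene. Symbols were updated through Entrez identifiers to the RefSeq annotation of GRCm38.p6 for 34754 probe sets, and 204 kept the annotation's symbol. Only probe sets with 1 symbol were used, and a gene was represented by its probe set of highest mean signal among 18193 genes. Other probe sets of a called gene that were bright differed in the opposite direction by over 0.5 on the log2 scale for 3 of 532 genes between DN3 and DN2, 19 of 804 between DN4 and DN3, and 68 of 1762 between DN4 and DN2.

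The design written before the data were examined assumed signals scaled between arrays. Means after trimming 2% at each end ranged from 129 to 233, so quantile normalization, planned as an alternative, was used throughout, and the absence of normalization was added as an alternative. The other settings, comparisons, gene lists and alternatives were chosen before the data were examined, except for the alternatives named as added. The offset added before taking log2 was the table's 25th percentile (signal 5.59). Genes were kept if they lay above the table-wide median (log2 4.69, signal 20.2) on at least 4 arrays, which left 11171. The number of arrays limits the precision.

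Group means of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison and a threshold of 0.05. A fold threshold of 2 was used for description. Lists of genes (34 with at least 3 measured members, of stage regulators, cell processes and markers of other cell types) were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists, with an estimated correlation and fry as alternatives. Array measures were compared by exact two-sided permutation tests, which do not use the pairing of arrays by sort. Genes highest or lowest in DN3 were those called in opposite directions at the successive steps. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.

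Genes were named by a rule fixed in advance. It took the sort markers, the 10 greatest rises and falls called in each comparison with the same direction in all 4 sorts (placeholder symbols passed over), up to 4 called members of each list with the smallest adjusted p, 5 genes each for the peak and trough patterns, and up to 3 of the brightest measured members of a marker list. Not every gene the rule allows is printed.

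Per the labels, samples of the same number share a source of cells. Deviations from the stage means correlated at 0.253 to 0.345 between arrays of the same sort, and among arrays of the other stages 12 of 12 arrays correlated best with those of their own sort, against at most 0.108 between sorts across stages. Arrays of sorts 1 and 2 against those of sorts 3 and 4 correlated at -0.123 or below across stages. Correlations of values within a stage were 0.969 to 0.985, and 0 pairs of arrays were identical. The fit with the sort as a block was an alternative.

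The fit was tested on simulated data with seeded changes. For DN3 against DN2 (10948 genes) 19.4%, 71.6% and 86.4% of genes seeded at log2 changes of 0.5, 1 and 2 were recovered, with 4 false calls among 10722 unchanged genes. For DN4 against DN3 (10955 genes) 16.4%, 58.2% and 90.9% were recovered, with 7 false calls among 10734. For DN4 against DN2 (10989 genes) 10.4%, 65.7% and 81.8% were recovered, with 7 among 10772. Camera called 0 of 33 unchanged lists in each. The noise was drawn independently for each probe set, without a sort effect, and the unchanged lists were random genes. These rates therefore do not cover real lists, whose genes can be correlated.

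Alternatives were the sort as a block, arrays centred on their median, an offset of 1 or a floor in place of the offset, no filter or a filter at the 75th percentile, every probe set by itself, the mean of all probe sets of a gene, probe sets that can match several transcripts left out, only the 8 arrays compared, eBayes with trend and robust settings, array weights, and leaving out each array in turn. Added after the data were seen were no between-array normalization, sorts 1 and 2 or sorts 3 and 4 only, the fit without the 3 arrays of lowest signal (DN2 replicate 2, DN4 replicates 1 and 2), and the block with the Gapdh 3'/5' ratio as a covariate.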

Results

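Transcript levels were measured in mouse thymocytes at 3 successive stages of early T cell development. These cells carry neither CD4 nor CD8 and are called double negative (DN). The DN2 stage was sorted as CD44+CD25+, DN3 as CD44-CD25+ and DN4 as CD44-CD25- cells, after magnetic depletion of CD4+ and CD8+ cells. Cells stained for CD4, CD8, CD3, NK1.1 or the gamma-delta T cell receptor were excluded. Thymuses came from female C57BL/6 mice aged 5 to 6 weeks. Each of 4 independent sorts pooled 4 mice, 16 in all, and gave 1 sample of each stage, so that 12 Affymetrix Mouse Genome 430 2.0 arrays fall into 3 groups of 4. The labels describe a profile of the stages, and the comparisons asked which transcripts differed between DN2 and DN3, between DN3 and DN4, and from DN2 to DN4.

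Of the genes on the array, 11171 passed the filter on dim signals. Fold changes are on the scale of log2(signal + offset) after quantile normalization, which understates the change of dim genes. In 36 of 154 called differences of named genes the lower stage lay below the filter level (log2 4.69), where the size of a difference depends on the offset. Linear folds of such genes are given as at least the fold against the filter level, beside the fitted log2 difference. Errors of log2 differences are standard errors from limma with n = 4 arrays per stage, and p-values are adjusted by the Benjamini-Hochberg method over all genes tested. Every gene described below as having risen or fallen moved that way in 4 of 4 sorts. The number of arrays limits the precision.

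The deposited signals were not on a common scale. Means of each array after trimming ranged from 129 to 233. The median signal was 22.2 ± 4.70 (SD, n = 4) in DN2, 22.5 ± 2.68 in DN3 and 16.9 ± 1.22 in DN4. The DN4 arrays were lower than the DN3 arrays by -0.41 on the log2 scale (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give, or 0.257 after adjustment over 18 such tests). The permutation ignores the pairing of arrays by sort, and an exact sign-flip test over 4 pairs can give no p under 0.125. The log2 ratio of the 3' over the 5' control probe sets for Gapdh, a sign of RNA shortening, was 1.39 ± 0.32 in DN2, 1.04 ± 0.17 in DN3 and 1.16 ± 0.21 in DN4. DN3 and DN2 differed by -0.35 (exact two-sided permutation p = 0.114, adjusted 0.514), and by -0.21 without DN2 replicate 2. The ratio was lower in DN3 than in DN2 in each sort, from 0.88 against 1.45 in sort 1 to 1.09 against 1.10 in sort 4. For beta-actin the ratio differed by -0.08 between DN3 and DN2 and by 0.06 between DN4 and DN3 (exact two-sided permutation p = 0.229 and 0.314, adjusted 0.514 each).

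**Figure D1:**
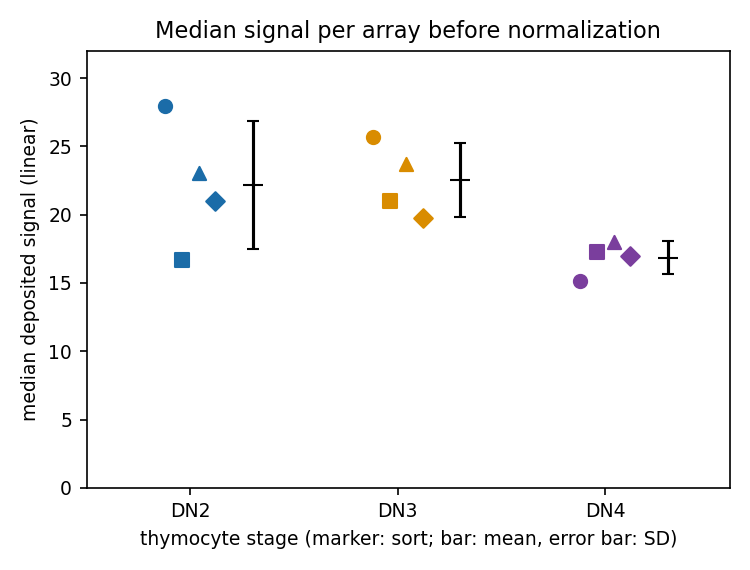
Median deposited signal (linear scale) of each of the 12 arrays by stage, before normalization. Points are arrays with a marker per sort, and bars give the mean and SD of 4 arrays; DN4 arrays lie between 15.1 and 18.0, and DN3 arrays between 19.7 and 25.7.

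The stages stood apart along the first principal component, which held 45.5% of the variance, and along the next, which held 13.3% and separated DN3 from the other stages. The component after these (11.2%) separated sorts 1 and 2 from sorts 3 and 4 within each stage. Calls within these pairs of sorts are therefore given beside the pooled counts.

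**Figure D2:**
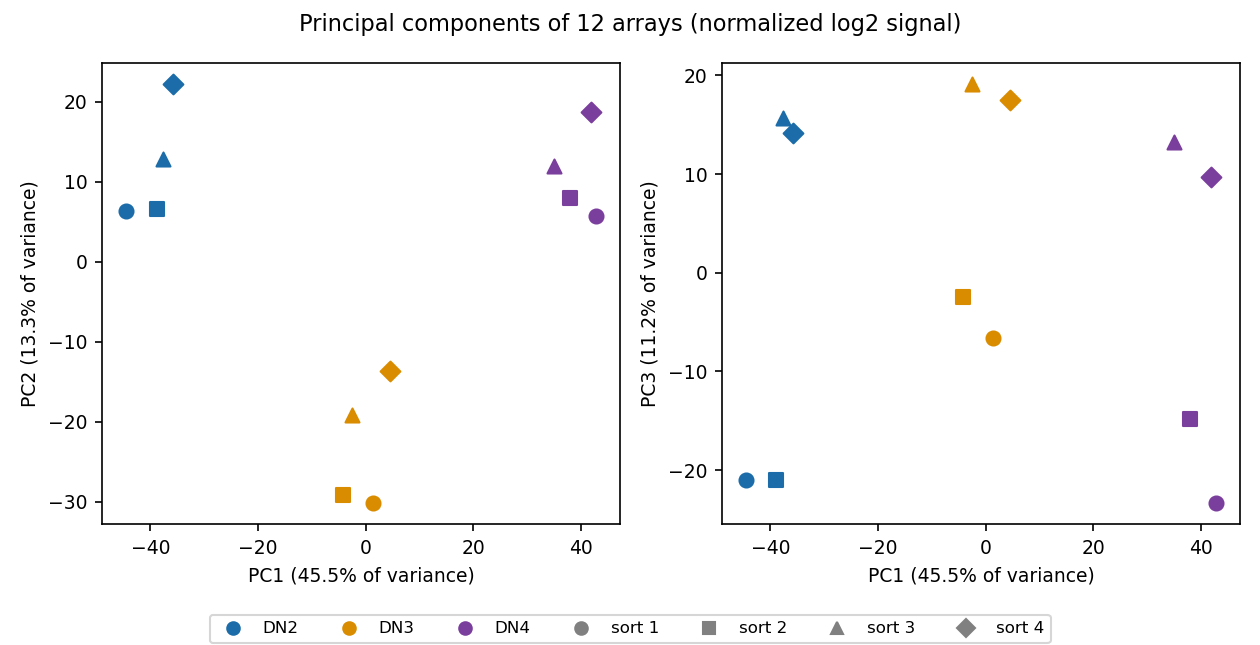
Principal components of the normalized log2 signals of 12 arrays, with colours for stages and markers for sorts. Axes give the share of variance (45.5%, 13.3% and 11.2%); on the vertical axis of the right panel the arrays of sorts 1 and 2 lie between -23.3 and -2.50, and those of sorts 3 and 4 between 9.73 and 19.1.

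From DN2 to DN3, 10 of 17 progenitor regulators fell and 0 rose, while 6 of 20 T-lineage transcription factors and 6 of 23 T cell receptor signalling genes rose, with 1 of each fallen. The camera test gave adjusted p = 0.00181, 0.177 and 0.212 with an estimated correlation for these lists. Cd44, used for the sort, fell by 3.70 ± 0.32 on the log2 scale (adjusted p = 1.55e-05). Cd3d, a subunit of the T cell receptor complex, rose 5.45-fold (2.45 ± 0.19, adjusted p = 6.46e-06) and Ptcra, the pre-T cell receptor alpha chain, rose 5.55-fold (2.47 ± 0.36, adjusted p = 9.67e-04). Rag1, which encodes a subunit of the V(D)J recombinase, rose 4.53-fold (2.18 ± 0.14, adjusted p = 1.83e-06), and the transcription factor gene Lef1 rose 11.2-fold (3.48 ± 0.14, adjusted p = 3.67e-08). Lyl1 and Hhex, which encode transcription factors of blood progenitors, fell by 4.38 ± 0.32 (adjusted p = 3.82e-06), to below the filter level, and by 3.97 ± 0.24 (adjusted p = 1.15e-06).

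Of 7 measured sort marker genes, 3 rose and 2 fell at this step. Cd3e rose by 0.88 ± 0.16 (adjusted p = 0.0043), and Cd8b1, the CD8 beta chain, was higher by 1.36 ± 0.30 (adjusted p = 0.0112) at log2 levels of 3.14 and 4.50, both below the filter level. Cd3g differed by 0.12 ± 0.10 (adjusted p = 0.533). Il2ra, which encodes CD25, the marker present on both populations, was lower in DN3 by -0.75 ± 0.22, a call at the edge of the threshold (adjusted p = 0.0485, or 0.0112 with the sort as a block). It was not called without any 1 of the DN2 or DN3 arrays, DN4 replicate 2 or DN4 replicate 3 (adjusted p = 0.054 to 0.126). The call also ended with arrays centred on their median, an offset of 1, a floor in place of the offset, no filter, or every probe set tested by itself.

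Among 20 measured T-lineage transcription factors, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone and 10 and 1 with the sort as a block. Ets2 rose by 2.15 ± 0.19 and Ikzf3, the Aiolos gene, by 2.16 ± 0.33 (adjusted p = 1.65e-05 and 0.00115), while Runx3 fell by 1.69 ± 0.23 (adjusted p = 5.47e-04). In the T cell receptor and pre-T cell receptor signalling list, 6 of 23 rose and 1 fell, or 8 and 2 adjusted over the list alone and likewise with the sort as a block. The kinase gene Zap70 rose by 1.66 ± 0.11 (adjusted p = 2.21e-06), although its 3 bright probe sets ranged from -0.16 to 1.66, and Syk, a kinase of the same family, fell by 0.84 ± 0.13 (adjusted p = 0.00161). Both lists lay above other genes in the camera test (adjusted p = 0.00316 each), with adjusted p = 0.177 and 0.212 with an estimated correlation. The double-positive stage list, named for the next stage of thymocytes, had 5 of 15 members higher and none lower by limma (6 and 0 adjusted over the list alone), with camera adjusted p = 7.14e-05, and adjusted p = 0.0901 with an estimated correlation.

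Among 11 Notch targets, 3 rose and 2, Il2ra and Nrarp, fell, over all genes and adjusted over the list alone (camera adjusted p = 0.178). Dtx1 rose by 2.41 ± 0.24 (adjusted p = 5.63e-05) and Notch3 by 0.90 ± 0.17 (adjusted p = 0.005), whereas Nrarp, an inhibitor of Notch signals, fell by 1.31 ± 0.19 (adjusted p = 7.54e-04). In the V(D)J recombination list 2 of 10 rose and 0 fell (2 and 0 adjusted over the list alone, 2 and 1 with the sort as a block, camera adjusted p = 0.171). Of 33 DNA replication genes 0 passed by limma, with 3 at an unadjusted p under 0.05, and of 29 mitosis genes 1 fell, or 0 of either list adjusted over the list alone (camera adjusted p = 0.14 and 0.43). With the sort as a block 1 and 3 rose and 2 and 1 fell. The DNA replication list passed the threshold without DN2 replicate 2 (0.0358) or DN3 replicate 4 (0.014), at a median that was -0.10 over all arrays and 0.07 without between-array normalization.

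Of 17 progenitor regulators, 10 fell and 0 rose, or 13 and 0 adjusted over the list alone, with a median log2 change of -1.53. The list lay below other genes with camera adjusted p = 5.74e-12, and adjusted p = 0.00181 with an estimated correlation. It was the 1 list called at this step under both. Cd34 fell by 4.48 ± 0.33 and Kit, the stem cell factor receptor, by 1.87 ± 0.19 (adjusted p = 4.28e-06 and 4.67e-05). The falls of greatest size in all 4 sorts included Ifitm1, at least 24.2-fold (-5.39 ± 0.22, adjusted p = 4.41e-08), and Il1r2, a decoy receptor for interleukin 1, 36.9-fold (-5.21 ± 0.44, adjusted p = 1.19e-05). Among the rises of greatest size were Scn4b, a sodium channel subunit, 15.9-fold (3.99 ± 0.32, adjusted p = 6.93e-06), H2-Q2, a class I-like gene, at least 7.80-fold (3.85 ± 0.36, adjusted p = 2.69e-05), and the kinase gene Camk4, 8.80-fold (3.14 ± 0.23, adjusted p = 4.46e-06, or 1.20 with the mean of its probe sets).

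Of 13 measured natural killer and innate genes, 7 fell and 2 rose, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.00316, and adjusted p = 0.118 with an estimated correlation). Cd244a and Tyrobp, a receptor and an adaptor of natural killer and myeloid cells, fell by 4.23 ± 0.41 and 3.61 ± 0.39 (adjusted p = 3.45e-05 and 1.05e-04), and Zbtb16, the PLZF gene, fell by 1.62 ± 0.17 (adjusted p = 8.4e-05). The granule protein genes moved apart, as Gzmb fell by 2.14 ± 0.36 and Gzma rose by 1.10 ± 0.22 (adjusted p = 0.00226 and 0.00709). The list was not called without DN2 replicate 3 (adjusted p = 0.117) or DN2 replicate 4 (adjusted p = 0.062). The filter was repeated without the array, so members above it only on the DN2 arrays could drop out. The list median was -1.25 over all arrays, and -0.33 and -0.38 in these fits. Of 21 cytokine receptors, 8 fell and 2 rose over all genes and adjusted over the list alone (camera adjusted p = 0.00538, and adjusted p = 0.0901 with an estimated correlation), with falls of 2.69 ± 0.38 in Il1r1 and 1.13 ± 0.20 in Il4ra (adjusted p = 7.54e-04 and 0.00325).

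Of 24 ribosome biogenesis genes 5 rose and 0 fell, or 18 and 0 adjusted over the list alone and 16 and 0 with the sort as a block, at a median of 0.43 (camera adjusted p = 1.08e-08, and adjusted p = 0.118 with an estimated correlation). Rrp9 rose by 0.92 ± 0.15, Bop1 by 0.73 ± 0.13 and Nolc1 by 0.68 ± 0.13 (adjusted p = 0.0019, 0.00264 and 0.00421). Of 19 cholesterol synthesis genes 7 rose and 0 fell, or 9 and 0 adjusted over the list alone and 2 and 0 without between-array normalization (camera adjusted p = 1.76e-04, and adjusted p = 0.177 with an estimated correlation). Msmo1, a sterol oxidase, rose by 0.91 ± 0.21 (adjusted p = 0.0138). Of 21 interferon response genes 2 fell and 0 rose, or 5 and 0 adjusted over the list alone and 7 and 0 with the sort as a block (camera adjusted p = 0.00193, and adjusted p = 0.195 with an estimated correlation). Oas1a, an interferon-induced RNA sensor, fell by 1.04 ± 0.17 (adjusted p = 0.00164). In the survival and apoptosis list 2 of 15 rose and 3 fell, or 2 and 5 adjusted over the list alone and likewise with the sort as a block (camera adjusted p = 0.353). Bmf and Bid, which promote cell death, rose by 1.52 ± 0.18 and 0.81 ± 0.13, and Bcl2, which opposes it, fell by 0.99 ± 0.20 (adjusted p = 2.08e-04, 0.00144 and 0.00769).

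Among markers of other blood cells, Cpa3, a carboxypeptidase of mast cell granules, fell 24.6-fold from a log2 level of 11.63 (-4.62 ± 0.38, adjusted p = 8.76e-06). The lysozyme genes Lyz1 and Lyz2, both held by the myeloid list, fell by 1.74 ± 0.35 and 1.46 ± 0.29 (adjusted p = 0.00655 and 0.00639). Of 3 mast cell markers 2 fell and of 12 myeloid markers 3 fell, with 0 risen in both, 2 and 4 fallen adjusted over the list alone and 2 and 5 with the sort as a block (camera adjusted p = 0.00316 each, and adjusted p = 0.0901 and 0.177 with an estimated correlation). Of 11 B cell, 9 dendritic cell and 11 mature alpha-beta T cell markers 1, 2 and 6 fell and 0, 0 and 1 rose, or 2, 2 and 6 fell and 0, 0 and 1 rose adjusted over the list alone, with 3, 2 and 6 fallen and 0, 0 and 1 risen with the sort as a block. The camera adjusted p of these lists was 0.0205, 0.00536 and 0.021, and adjusted p = 0.212, 0.34 and 0.19 with an estimated correlation. Cd52, of the mature T cell list, fell by 1.72 ± 0.35 (adjusted p = 0.00741). Of 5 natural killer cell markers 3 fell and 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.212). H2-Aa and H2-Ab1, MHC class II chains of antigen-presenting cells, were lower by -1.49 ± 0.57 and -0.62 ± 0.28 (adjusted p = 0.126 and 0.195), and H2-Aa passed the threshold without DN4 replicate 1 (adjusted p = 0.01). Cd79b, a B cell receptor subunit, differed by -0.20 ± 0.16 (adjusted p = 0.508). Of 7 gamma-delta T cell markers 2 fell and 0 rose, or 2 and 1 adjusted over the list alone and 3 and 1 with the sort as a block (camera adjusted p = 0.0615), and the list passed the threshold without DN2 replicate 4 (0.0299), DN3 replicate 2 (0.0239) or DN4 replicate 4 (0.0491). The call of the B cell list ended without DN2 replicate 3, DN2 replicate 4 or DN3 replicate 4 (adjusted p = 0.0509, 0.062 and 0.0663). That of the dendritic cell list ended without DN2 replicate 1, 3 or 4 or DN3 replicate 1 (0.189, 0.163, 0.209 and 0.064). That of the mature T cell list ended with the sort as a block (0.0813) and without DN2 replicate 2 or DN3 replicate 2 (0.0549 and 0.0504). The filter was repeated where an array was left out, so members could drop out. The median of the dendritic cell list was -0.89 over all arrays, and -0.53, -0.58, -0.46 and -0.46 in the fits that ended its call.

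In total 1257 genes were called between DN3 and DN2 by limma, 533 higher and 724 lower, of which 147 and 311 differed at least 2-fold. With the sort as a block 2332 were called, 1252 of them shared with the fit without it. In sorts 1 and 2 alone 256 genes were called, and in sorts 3 and 4 alone 434. With the Gapdh 3'/5' ratio as a covariate beside the block 397 were called, while Il1r2 was at -4.61, Cd244a at -5.05 and Tyrobp at -4.46. The calls of 12 named genes ended in that fit, where the standard error was larger for 12 of them and the change smaller for 7 and larger for 5. These were Il2ra (-0.75 ± 0.22, then -0.76 ± 0.30), Cd8b1 (1.36 ± 0.30, then 1.18 ± 0.58), Syk (-0.84 ± 0.13, then -0.72 ± 0.18), Notch3 (0.90 ± 0.17, then 0.88 ± 0.21), Il4ra (-1.13 ± 0.20, then -1.03 ± 0.28) and Oas1a (-1.04 ± 0.17, then -0.89 ± 0.24). The others were Lyz1 (-1.74 ± 0.35, then -1.77 ± 0.67), Lyz2 (-1.46 ± 0.29, then -1.24 ± 0.42), Cd52 (-1.72 ± 0.35, then -2.29 ± 0.50), Gzma (1.10 ± 0.22, then 1.21 ± 0.37), Bst1 (1.98 ± 0.24, then 1.51 ± 0.40) and Arhgef10l (2.05 ± 0.39, then 2.27 ± 0.70). Over all genes the median standard error was 0.18, or 0.13 with the block and 0.21 with the block and the covariate, at 9, 6 and 5 residual degrees of freedom. Without between-array normalization 604 were called, and the calls of Il2ra, Syk and Bcl2 ended. With the mean of all probe sets of a gene, those of Il2ra, Ikzf3, Runx3, Bcl2 and Lyz1 ended. That mean also made the fold over 1.5 times smaller for Cd44 (-2.31), Kit (-1.22), Cd244a (-3.13), Zap70 (0.89), Ikzf3 (0.67), Runx3 (-0.48) and Lyz1 (-0.94). H2-Aa passed the threshold with only the 8 arrays compared and without the 3 arrays of lowest signal. Counts of called members of the lists that camera called also moved by over 1.5 times. Without between-array normalization 3 ribosome biogenesis genes rose, 5 cytokine receptors fell and 0 rose, 1 interferon response gene and 1 mast cell marker fell, 1 innate gene rose and 0 signalling genes fell. Without the 3 arrays 1 cytokine receptor rose, 4 innate genes fell and 1 rose, and 4 interferon response genes and 2 B cell, 5 myeloid and 5 dendritic cell markers fell, and the camera call of the innate list ended (0.0704). That fit repeated the filter, so lower counts can also come from members no longer tested. Cd244a of the innate list, Cd34, Lyl1, Ifitm1 and Cd8b1 were not tested there. With the block and covariate 1 cholesterol synthesis, 5 signalling and 3 double-positive stage genes rose, 0 signalling genes fell, 2 cytokine receptors and 5 innate genes fell with 0 risen, and 0 interferon response genes passed by limma, with 3 at an unadjusted p under 0.05. In that fit 0 B cell and 1 each of the myeloid, dendritic, mast and mature T cell markers fell, and the calls of the cytokine receptor and mature T cell lists ended (0.0504 and 0.162). With arrays centred on their median 2 B cell markers fell. The filter at the 75th percentile ended the calls of the innate, cytokine receptor, dendritic cell and mature T cell lists (0.31, 0.0944, 0.31 and 0.117). The mean of all probe sets ended those of the cytokine receptor and mature T cell lists (0.157 and 0.0824), and no filter those of the B cell and mast cell lists (0.0516 and 0.137).

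**Figure D3:**
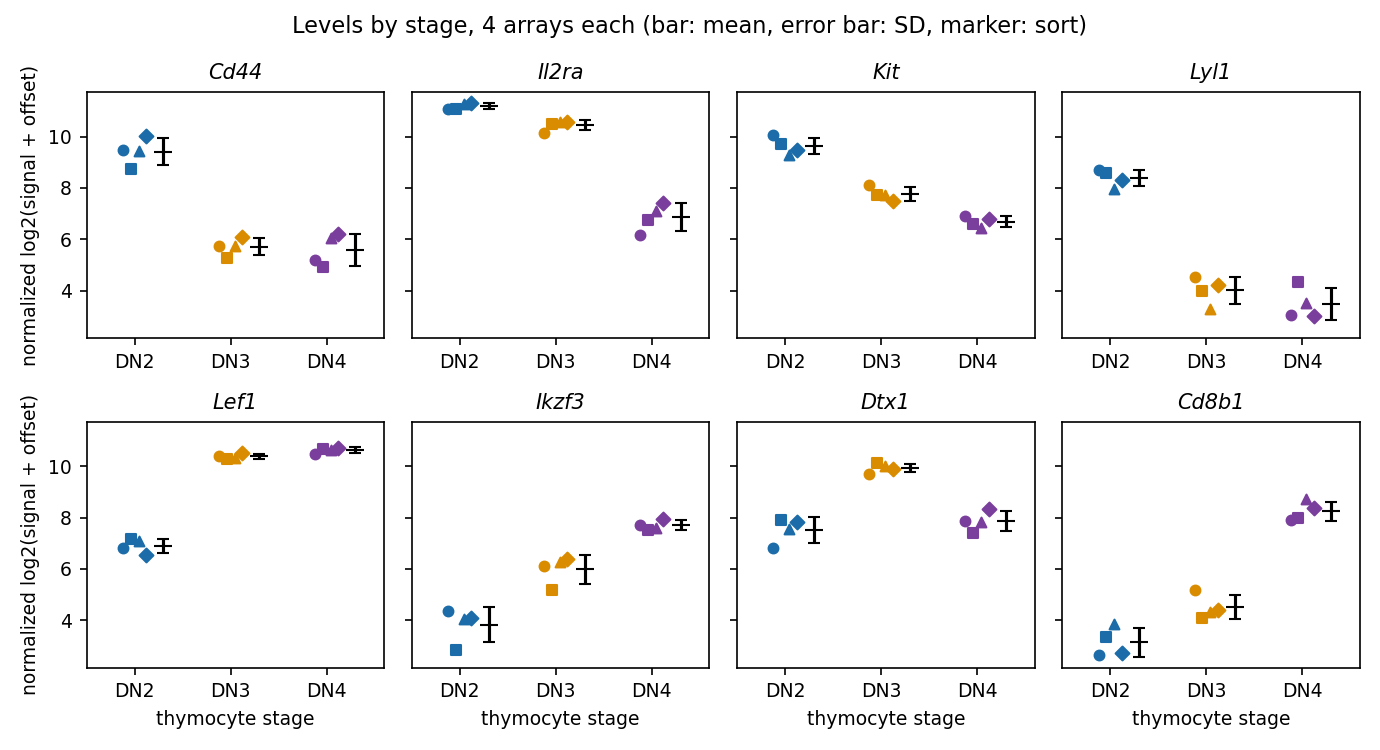
Normalized log2(signal + offset) of 8 genes by stage, with points for the 12 arrays, a marker per sort, and bars for the mean and SD of 4 arrays. Cd44, Kit and Lyl1 fell from DN2 to DN3, Lef1 rose, Il2ra and Dtx1 fell and Cd8b1 rose from DN3 to DN4, and Ikzf3 rose at both steps.

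From DN3 to DN4, 4 of 11 Notch targets fell, among them Il2ra, which encodes the CD25 used for the sort. Of the DNA replication genes 18 of 33, and of the mitosis genes 14 of 29, rose relative to the other genes. The camera test gave adjusted p = 0.138, 0.31 and 0.359 with an estimated correlation for these lists. Il2ra fell by 3.58 ± 0.22 (adjusted p = 2.14e-06), and Cd44, absent from the gate of both stages, differed by -0.13 ± 0.32 (adjusted p = 0.817). Cd8b1 rose at least 10.8-fold, to a log2 level of 8.25 (3.75 ± 0.30, adjusted p = 1.59e-05), in cells sorted as negative for surface CD8. Erg, a progenitor transcription factor gene, fell at least 6.54-fold (-4.48 ± 0.20, adjusted p = 3.36e-07), and Dtx1 fell 4.21-fold (-2.08 ± 0.24, adjusted p = 2.55e-04).

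Of 11 Notch targets 4 fell and 0 rose, or 5 and 0 adjusted over the list alone, at a median of -0.76. Il2ra, whose product CD25 defined the gate, is among the 4 and adds to the count, the median and the list test. The list lay below other genes with camera adjusted p = 3.3e-05, and adjusted p = 0.138 with an estimated correlation. Notch3 fell by 1.39 ± 0.17 (adjusted p = 3.25e-04). Of 17 progenitor regulators 4 fell and 1 rose, or 6 and 1 adjusted over the list alone and 6 and 2 with the sort as a block (camera adjusted p = 0.00262, and adjusted p = 0.125 with an estimated correlation). Beside Erg, Mycn changed by -2.11 ± 0.21, Nfe2 by -2.01 ± 0.39 and Kit by -1.08 ± 0.19 (adjusted p = 8.56e-05, 0.00476 and 0.00246). Other falls of great size were those of Khdc1a, 27.1-fold (-4.76 ± 0.75, adjusted p = 0.00163), Ctla2a, 19.3-fold (-4.27 ± 0.23, adjusted p = 9.71e-07), Pld4, 19.0-fold (-4.25 ± 0.28, adjusted p = 3.36e-06), and Tshz2, at least 8.05-fold (-3.82 ± 0.22, adjusted p = 1.36e-06). The difference of Khdc1a was -4.03 without DN4 replicate 1, -5.41 without DN4 replicate 3 and -3.53 without the 3 arrays of lowest signal.

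Of the DNA replication genes 18 rose relative to other genes and 0 fell, or 26 and 0 adjusted over the list alone, at a median of 0.55. Of the mitosis genes 14 rose in the same sense and 0 fell, or 23 and 0 adjusted over the list alone and 25 and 0 with the sort as a block, at a median of 0.60. The camera adjusted p was 1.17e-09 for replication and 1.06e-08 for mitosis, with adjusted p = 0.31 and 0.359 with an estimated correlation. Gins2, of the replicative helicase, rose by 0.76 ± 0.12, and Ccne1, the cyclin E1 gene, by 0.91 ± 0.16 (adjusted p = 0.00123 and 0.0025). Ccnb2 and Ccna2, mitotic cyclins, rose by 0.88 ± 0.16 and 0.71 ± 0.15, and Cdk1, their kinase, by 0.73 ± 0.18 (adjusted p = 0.00319, 0.00832 and 0.0179). Without between-array normalization the medians of these lists were 0.19 and 0.16, above a shift of -0.41 in the median of all genes, and limma called 0 members of either list, with 2 and 0 at an unadjusted p under 0.05. Of the replication and mitosis genes 5 and 4 rose without the 3 arrays of lowest signal, 32 and 22 with arrays centred on their median, and 27 mitosis genes with the block and the Gapdh 3'/5' covariate.

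Cell cycle inhibitors and D cyclins went both ways after quantile normalization, with 5 of 17 higher and 3 lower, or 6 and 4 adjusted over the list alone and 6 and 5 with the sort as a block, with camera adjusted p = 0.83. Without between-array normalization 0 were higher and 5 lower. Cdkn1a, the p21 inhibitor gene, fell by 2.65 ± 0.36, Ccnd2 by 1.45 ± 0.19 and Cdk6 by 0.72 ± 0.13, while Cdkn2c rose by 0.65 ± 0.10 (adjusted p = 6.24e-04, 5.39e-04, 0.00405 and 0.00169). Of 15 survival and apoptosis genes 3 fell and 1 rose, or 4 and 3 adjusted over the list alone and likewise with the sort as a block (camera adjusted p = 0.326). Bcl2 fell by 1.73 ± 0.20, Il7r, the interleukin 7 receptor, by 1.06 ± 0.14 and Bmf by 1.11 ± 0.18, while Bid rose by 0.79 ± 0.13 (adjusted p = 2.55e-04, 4.52e-04, 0.00195 and 0.00169). Of 21 cytokine receptors 9 fell and 0 rose, or 10 and 3 adjusted over the list alone. The 9 include Il2ra, the gene of the sort marker CD25, and Il4ra, which fell by 1.68 ± 0.20 (adjusted p = 2.86e-04). The camera adjusted p of the list was 0.0052, and adjusted p = 0.125 with an estimated correlation.

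T cell surface genes rose or fell by gene. Cd2, Cd6 and Cd81 rose by 2.44 ± 0.33, 1.30 ± 0.14 and 1.24 ± 0.17 (adjusted p = 5.43e-04, 1.65e-04 and 5.82e-04), while Cd3e and Cd3g fell by 0.72 ± 0.16 and 0.88 ± 0.10 (adjusted p = 0.0122 and 2.15e-04). In the signalling list 3 of 23 rose and 5 fell, or 3 and 8 adjusted over the list alone and 4 and 9 with the sort as a block (camera adjusted p = 0.233). In the double-positive stage list 4 of 15 rose and 1, Rag1, fell (by 0.76 ± 0.14, adjusted p = 0.00398), or 4 and 2 adjusted over the list alone and 4 and 4 with the sort as a block (camera adjusted p = 0.647). Without between-array normalization 3 rose and 4 fell, at a median of -0.38. Relative to other genes the list then lay higher in camera (adjusted p = 0.0372). Of 20 T-lineage transcription factors 2 rose and 4 fell, or 2 and 6 adjusted over the list alone and 2 and 10 with the sort as a block (camera adjusted p = 0.095, or 0.0417 with the sort as a block, and adjusted p = 0.401 with an estimated correlation), at a median of -0.19 that was 0.09 with arrays centred on their median. Ikzf3 rose by 1.71 ± 0.33 and Id3, a gene induced by pre-T cell receptor signals, by 1.13 ± 0.27 (adjusted p = 0.00458 and 0.0141). Runx1 fell by 1.11 ± 0.16 (adjusted p = 0.00102), although its 6 bright probe sets ranged from -1.37 to 0.69. In the T cell receptor early response list 1 of 15 rose and 2 fell, or 1 and 3 adjusted over the list alone and 1 and 5 with the sort as a block (camera adjusted p = 0.233). Rises of great size outside these groups were those of Pdlim4, by 2.66 ± 0.38, and Adgre5, which encodes CD97, by 1.74 ± 0.19 (adjusted p = 8.54e-04 and 2.1e-04).

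Among natural killer and innate genes, Nkg7, a granule protein gene, fell by 2.86 ± 0.17, Gzmb by 2.08 ± 0.36 and Cd7 by 1.74 ± 0.31 (adjusted p = 2.14e-06, 0.00264 and 0.00322), while Gzma was at a log2 level of 12.97 in DN4 (0.31 ± 0.22, adjusted p = 0.373). Of 5 natural killer cell markers 3 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0323, and adjusted p = 0.2 with an estimated correlation). That call ended with the sort as a block (0.0532) and without DN3 replicate 4 (0.0508) or DN4 replicate 3 (0.0564). In the wider innate list 4 of 13 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.053, and adjusted p = 0.31 with an estimated correlation). It passed the threshold, at 0.0196 to 0.0417, without any 1 of the DN2 arrays, DN3 replicate 1, 2 or 4, or DN4 replicate 1 or 3. Array weights, centring, a floor, the mean of all probe sets, no filter, and leaving out probe sets that can match several transcripts or the 3 arrays of lowest signal also brought it past the threshold (0.026 to 0.0439). Of 21 interferon response genes 5 fell and 1 rose, or 9 and 1 adjusted over the list alone and 10 and 1 with the sort as a block (camera adjusted p = 0.00262, and adjusted p = 0.31 with an estimated correlation). Gbp2 fell by 1.02 ± 0.17, Zbp1 by 1.35 ± 0.25 and Iigp1 by 0.77 ± 0.16, whereas Ifit2 rose by 0.94 ± 0.20 (adjusted p = 0.00216, 0.00426, 0.00832 and 0.009).

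Of 24 ribosome biogenesis genes 2 rose and 0 fell, or 1 and 0 adjusted over the list alone and 6 and 0 with the sort as a block, at a median of 0.17 that was -0.15 without between-array normalization. The list's camera adjusted p was 0.0167, with adjusted p = 0.474 with an estimated correlation, and the call ended without DN4 replicate 4 (0.0566) or the 3 arrays of lowest signal (0.0504). Polr1b, a subunit of RNA polymerase I, rose by 0.69 ± 0.12 (adjusted p = 0.0025). Without between-array normalization 0 members passed by limma, with 1 at an unadjusted p under 0.05. With arrays centred on their median 7 rose, 4 with the block and the Gapdh covariate and 1 without the 3 arrays.

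Among markers of other cell types, Cpa3 fell by 1.70 ± 0.38 and Lyz1 fell by 3.07 ± 0.35 (adjusted p = 0.0106 and 2.15e-04), and Car2, a carbonic anhydrase of red cell precursors, fell by 0.94 ± 0.19 (adjusted p = 0.00574). Epcam and Cdh1, adhesion molecules of epithelia, fell by 1.68 ± 0.31 and 2.83 ± 0.25 (adjusted p = 0.00359 and 4.08e-05). H2-Aa and H2-Ab1 were higher in DN4 by 1.55 ± 0.57 and 0.78 ± 0.28 (adjusted p = 0.086 and 0.0775). They passed the threshold with the sort as a block (0.0352 and 0.029) and without DN4 replicate 1 (0.00208 and 0.0324). Both also passed it with array weights and without the 3 arrays of lowest signal, and H2-Ab1 with the filter at the 75th percentile or eBayes with trend and robust settings. Of 9 dendritic cell markers 1 rose and 0 fell, or 7 and 1 adjusted over the list alone and 6 and 1 with the sort as a block (camera adjusted p = 0.0763), and the list passed the threshold without any 1 of the DN2 arrays (0.00567 to 0.0106), DN3 replicate 3 (0.0191) or DN4 replicate 1 (6.91e-04). It did so as well without between-array normalization (1.84e-04), without the 3 arrays of lowest signal (5.32e-06), and with array weights, a floor or an offset of 1, the mean of all probe sets or no filter (0.0319 to 0.042). Of 3 mast cell and 12 myeloid markers 1 and 2 fell and 0 rose, and of 11 B cell markers 2 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.149, 0.15 and 0.382), with 1 B cell marker fallen with the sort as a block.

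In total 1818 genes were called between DN4 and DN3 by limma, 806 higher and 1012 lower, of which 82 and 393 differed at least 2-fold. Without DN3 replicate 2 there were 1129. With the sort as a block 3388 were called, 1815 of them shared with the fit without it. In sorts 1 and 2 alone 231 genes were called, and in sorts 3 and 4 alone 233. The split depended on the scaling. It was 1709 higher and 861 lower with arrays centred on their median, which shifted the median of all genes by 0.17, and 39 higher and 2837 lower without between-array normalization. Of the genes named here, the latter ended the calls of Id3, Gins2, Ccne1, Ccnb2, Cdk1, Ccna2, Cdkn2c, Bid, Ifit2, Polr1b and Trem1. Centring ended those of Rag1 and Cdk6 and added that of Gzma, and the mean of all probe sets of a gene ended that of Bmf. The Gapdh 3'/5' covariate with the block ended that of Id3, whose change of 1.13 ± 0.27 became 0.92 ± 0.28. Without the 3 arrays of lowest signal 905 genes were called, and the calls of Ccna2, Zbp1, Ifit2, Cpa3, Trem1 and Car2 ended, while Nfe2 was at -2.77. Cd8b1 and Pdlim4 did not pass the repeated filter of that fit and were not tested in it. The mean of all probe sets made the fold over 1.5 times smaller for Dtx1, Erg (-2.41), Mycn (-1.18), Ikzf3 (1.02), Runx1 (-0.44) and Lyz1 (-1.17). Counts of other lists that camera called moved by over 1.5 times as well. Without between-array normalization 9 Notch targets fell, 9 progenitor regulators fell and 0 rose, and 15 interferon response genes fell and 0 rose, and the camera call of the progenitor regulators ended (0.0509). When the 3 arrays were left out 2 interferon response genes fell and 0 rose, and 0 progenitor regulators rose. With the block and covariate 7 Notch targets fell and 1 cytokine receptor rose, and with arrays centred on their median 1 cytokine receptor and 1 natural killer cell marker rose.

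**Figure D4:**
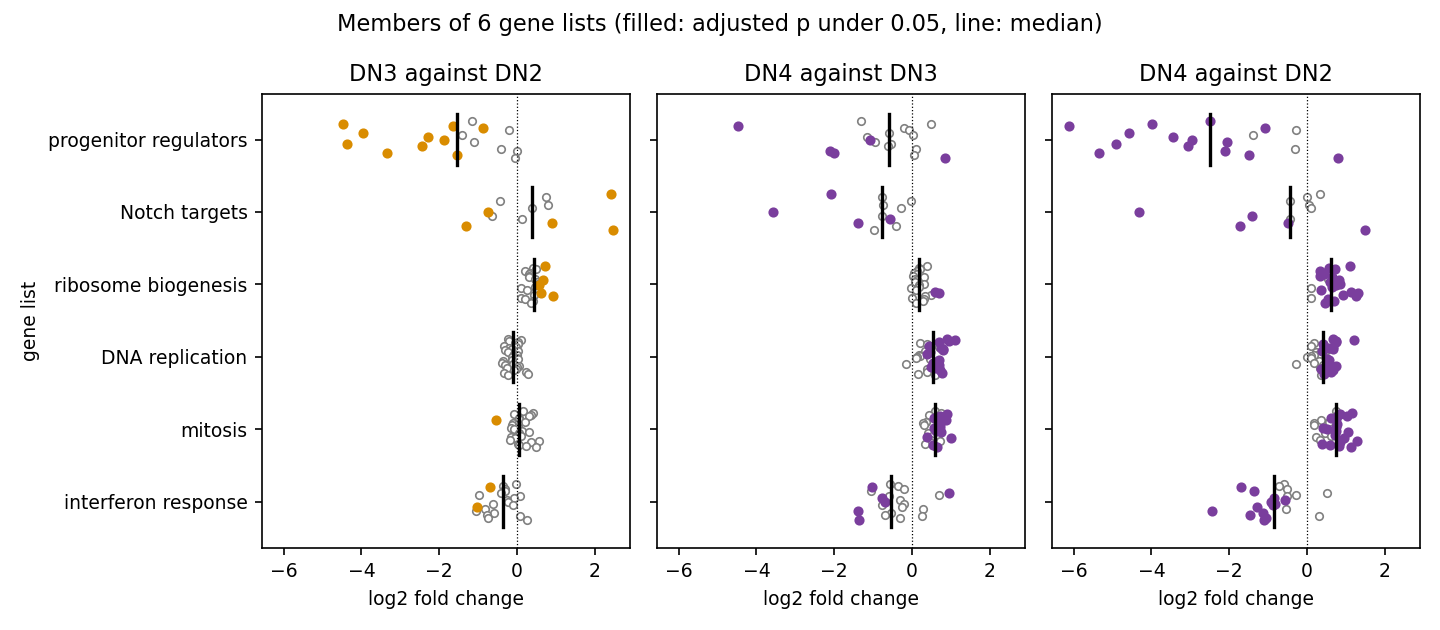
Log2 fold change of each measured member of 6 gene lists in the 3 comparisons, with filled points for adjusted p under 0.05 by limma and black lines for list medians. DNA replication and mitosis members lie above 0 from DN3 to DN4 (medians 0.55 and 0.60, or 0.19 and 0.16 without between-array normalization), and progenitor regulators lie below it from DN2 to DN3 (median -1.53).

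Some genes were highest or lowest in DN3. Rising into DN3 and falling out of it were 107 genes, among them Scn4b (3.99 ± 0.32, then -3.93 ± 0.32), Afdn, the afadin gene of cell junctions (2.73 ± 0.21, then -2.22 ± 0.21), Dtx1, Arhgef10l (2.05 ± 0.39, then -2.08 ± 0.39) and Bst1 (1.98 ± 0.24, then -3.37 ± 0.24). The reverse was seen in 45 genes, among them Gsn, the gelsolin gene (-1.83 ± 0.40, then 2.33 ± 0.40), and Trem1 (-1.28 ± 0.28, then 1.17 ± 0.28). Arhgef10l lay below the filter level in DN2 and DN4, and Trem1 in DN3, where the size of a difference depends on the offset. Against the filter level the changes were at least 0.68 at each step for Arhgef10l, and at least 0.49 and 0.38 for Trem1. The call of Gsn from DN2 to DN3 ended without probe sets that can match several transcripts (-0.96, then 1.38). With the mean of all probe sets the changes were 1.30 then -1.06 for Afdn, 1.36 then -2.72 for Bst1 and -0.96 then 1.35 for Gsn, and with the block and the Gapdh covariate those into DN3 were -2.54 for Gsn and -2.27 for Trem1. With the sort as a block the counts were 237 and 161. Without DN3 replicate 2 they were 65 and 25, and without DN3 replicate 1 the latter was 24. Both steps share the DN3 arrays. Independent lists of the lengths observed would share 48.3 and 52.2, the latter above the 45 found. Simulated arrays with no effect gave 0 such genes, with at most 1 gene called at either step. With so few calls the 0 was given in advance, so it is no test of these patterns. With the DN3 arrays split 6 ways, so that each step used other DN3 arrays, 29 to 45 and 3 to 13 genes were called, where independent lists of those lengths would share 8.76 to 17.0 and 6.90 to 24.5. A further 88 genes rose at both steps and 186 fell at both, against 38.5 and 65.6 for independent lists, or 16 to 56 and 66 to 138 with the DN3 arrays split, against 4.14 to 14.8 and 13.7 to 31.0. Across 11171 genes, which are not independent replicates, the log2 changes of the steps correlated at 0.0786, against -0.497 in simulations with no effect and 0.155 with the DN3 arrays split. The covariance was 0.0202 against -0.0245 in the simulations.

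From DN2 to DN4, H2-Q2 rose at least 24.0-fold (5.47 ± 0.36, adjusted p = 5.38e-07), Cd8b1 at least 11.8-fold (5.11 ± 0.30, adjusted p = 2.02e-07), Camk4 23.3-fold (4.54 ± 0.23, adjusted p = 6.94e-08) and Cd2 at least 7.44-fold (4.02 ± 0.33, adjusted p = 2.89e-06). Serpinb1a, a protease inhibitor gene, fell by 6.66 ± 0.32 (adjusted p = 3.54e-08), and Cpa3 by 6.32 ± 0.38 (adjusted p = 2.39e-07). Erg fell at least 20.4-fold (-6.12 ± 0.20, adjusted p = 3.07e-09), and Scin, an actin-severing protein gene, fell 61.3-fold (-5.94 ± 0.26, adjusted p = 2.44e-08).

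Of 17 progenitor regulators 13 fell and 1 rose, or 14 and 1 adjusted over the list alone, at a median of -2.48. The camera adjusted p was 1.22e-09, and adjusted p = 0.00414 with an estimated correlation, which no other list passed in this comparison. Nfe2 fell by 5.35 ± 0.39, Lyl1 by 4.91 ± 0.32 and Kit by 2.95 ± 0.19 (adjusted p = 1.15e-06, 5.03e-07 and 3.7e-07). In the double-positive stage list 7 of 15 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.00194, and adjusted p = 0.166 with an estimated correlation). Rag1 rose by 1.42 ± 0.14 and Ets2 by 2.26 ± 0.19 (adjusted p = 1.57e-05 and 3.42e-06). Of the signalling genes 7 of 23 rose and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.483), with Zap70 up by 2.28 ± 0.11 (1.68 without DN3 replicate 3) and Cd6 by 1.82 ± 0.14, and Syk down by -1.36 ± 0.13 (adjusted p = 4.2e-08, 1.66e-06 and 1.31e-05). Of the T-lineage transcription factors 5 of 20 rose and 3 fell, or 6 and 3 adjusted over the list alone and 5 and 6 with the sort as a block (camera adjusted p = 0.699), with Lef1 up by 3.73 ± 0.14 and Runx3 down by -2.31 ± 0.23 (adjusted p = 5.38e-09 and 1.5e-05). Of the Notch targets 1 of 11, Ptcra, rose (1.49 ± 0.36, adjusted p = 0.00779) and 4 fell, including Nrarp by 1.71 ± 0.19 (adjusted p = 3.11e-05). Adjusted over the list alone there were likewise 1 and 4 (camera adjusted p = 0.106). Il2ra, the gene of the sort marker CD25, is a member of this list and of the cytokine receptor list.

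Mitosis genes rose in 20 of 29 and DNA replication genes in 17 of 33, with 0 fallen in either, or 20 and 19 risen adjusted over the list alone. The camera adjusted p was 2.04e-06 and 1.19e-04, and adjusted p = 0.356 and 0.408 with an estimated correlation. Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose by 1.13 ± 0.19 (adjusted p = 6.84e-04). Without between-array normalization, which shifted the median of all genes by -0.29, the medians were 0.42 and 0.21 and limma called 2 and 0 members, with 8 and 4 at an unadjusted p under 0.05. Without the 3 arrays of lowest signal 9 and 5 rose, and with arrays centred on their median 30 replication genes. Ribosome biogenesis genes rose in 21 of 24 with 0 fallen, or 22 and 0 adjusted over the list alone, 5 and 0 without between-array normalization and 10 and 0 without the 3 arrays (camera adjusted p = 1.32e-07, and adjusted p = 0.159 with an estimated correlation), with Polr1b up by 1.30 ± 0.12 and Rrp9 by 1.27 ± 0.15 (adjusted p = 7.32e-06 and 5.96e-05). Of 21 interferon response genes 13 fell and 0 rose, or 16 and 1 adjusted over the list alone and 15 and 2 with the sort as a block (camera adjusted p = 1.34e-05, and adjusted p = 0.156 with an estimated correlation), among them Oasl2 by 2.45 ± 0.41 and Gbp2 by 1.71 ± 0.17 (adjusted p = 7.42e-04 and 1.55e-05). Of 19 cholesterol synthesis genes 9 rose and 0 fell, over all genes and adjusted over the list alone, at a median of 0.40 that was -0.05 without between-array normalization (camera adjusted p = 0.00456, and adjusted p = 0.313 with an estimated correlation). Without normalization limma called 0 of them, with 1 at an unadjusted p under 0.05, and 2 rose without the 3 arrays. Pmvk, a kinase of the mevalonate pathway, rose by 1.08 ± 0.19, Insig1 by 0.80 ± 0.16 and Sqle, squalene epoxidase, by 0.64 ± 0.16 (adjusted p = 0.00118, 0.00209 and 0.00944).

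Of 13 natural killer and innate genes 8 fell and 1, Gzma, rose (by 1.40 ± 0.22, adjusted p = 4.87e-04), or 9 and 1 adjusted over the list alone (camera adjusted p = 5.7e-04, and adjusted p = 0.102 with an estimated correlation). Nkg7 fell by 4.47 ± 0.17 and Gzmb by 4.22 ± 0.36 (adjusted p = 8.03e-09 and 4.04e-06). Of 21 cytokine receptors 10 fell and 0 rose, or 10 and 3 adjusted over the list alone and likewise with the sort as a block (camera adjusted p = 0.00187, and adjusted p = 0.0853 with an estimated correlation), with Il4ra down by -2.81 ± 0.20 and Il7r by -1.55 ± 0.14 (adjusted p = 1.09e-06 and 5.51e-06). In the survival and apoptosis list 1 of 15 rose and 4 fell, over all genes and adjusted over the list alone, or 2 and 5 with the sort as a block (camera adjusted p = 0.414), with Bcl2 down by -2.72 ± 0.20 and Bid up by 1.61 ± 0.13 (adjusted p = 1.47e-06 and 2.28e-06). Cdkn1a fell by 3.41 ± 0.36 (adjusted p = 2.49e-05) in the list of D cyclins and inhibitors, where 3 of 17 rose and 4 fell, or 5 and 4 adjusted over the list alone and 7 and 4 with the sort as a block (camera adjusted p = 0.881). Without between-array normalization 0 rose and 4 fell.

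Of 12 myeloid markers 5 fell and 0 rose, or 5 and 1 adjusted over the list alone and 7 and 1 with the sort as a block, with Lyz1 down by -4.82 ± 0.35 and Lyz2 by -2.53 ± 0.29 (adjusted p = 1.15e-06 and 4.49e-05). All 3 measured mast cell markers fell, over all genes and adjusted over the list alone, Hdc by 1.89 ± 0.46 and Gata2 by 1.07 ± 0.25 beside Cpa3 (adjusted p = 0.00777 and 0.0056). In DN4 Hdc and Gata2 lay below the filter level. Of 7 gamma-delta T cell markers 2 fell and 0 rose, over all genes and adjusted over the list alone, or 4 and 0 with the sort as a block. The camera adjusted p of these lists was 0.00456, 0.00588 and 0.0153, and adjusted p = 0.221, 0.102 and 0.344 with an estimated correlation. Of 11 B cell, 9 dendritic cell and 5 natural killer cell markers 3, 2 and 3 fell and 0, 1 and 1 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.465, 0.881 and 0.0714). Of 11 mature alpha-beta T cell markers 5 fell and 1 rose, or 6 and 1 adjusted over the list alone and 5 and 2 with the sort as a block (camera adjusted p = 0.0944). The natural killer and mature T cell lists passed the threshold with arrays centred on their median (0.0372 and 0.0332). H2-Aa differed by 0.06 ± 0.57 and H2-Ab1 by 0.16 ± 0.28 (adjusted p = 0.948 and 0.682), and Cd79b fell by 0.59 ± 0.16 (adjusted p = 0.0137).

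In total 3864 genes were called between DN4 and DN2 by limma, 2002 higher and 1862 lower, of which 367 and 853 differed at least 2-fold. In sorts 1 and 2 alone 1900 genes were called, and in sorts 3 and 4 alone 2253. The split was 2964 higher and 1528 lower with arrays centred on their median, which shifted the median of all genes by 0.19, and 287 higher and 2742 lower without between-array normalization. Of the genes named here, the latter ended the calls of Pmvk, Insig1 and Sqle. Without the 3 arrays of lowest signal 2392 genes were called, and the calls of Insig1, Gata2 and Cd79b ended. The repeated filter of that fit left 48 of the 50 genes named in this comparison. The Gapdh 3'/5' covariate with the block ended those of Insig1, whose change of 0.80 ± 0.16 became 0.44 ± 0.16, and Gata2, whose change of -1.07 ± 0.25 became -0.84 ± 0.35. The mean of all probe sets ended that of Runx3. That mean made the fold over 1.5 times smaller for Camk4 (2.04), Serpinb1a (-4.78), Erg (-3.60), Kit (-2.03), Runx3 (-0.79), Zap70 (1.33), Bcl2 (-1.68) and Lyz1 (-2.11), and without the 3 arrays Nfe2 was at -6.20 and Hdc at -2.50. Counts of other lists that camera called moved by over 1.5 times without between-array normalization, where 0 progenitor regulators rose and 8 myeloid and 6 gamma-delta T cell markers fell. In the fit without the 3 arrays 5 innate genes and 3 myeloid markers fell, and the camera call of the gamma-delta T cell list ended (0.0918). The filter at the 75th percentile ended the calls of the innate, gamma-delta T cell and myeloid lists (0.217, 0.106 and 0.0507), the mean of all probe sets that of the gamma-delta T cell list (0.127) and no filter that of the mast cell list (0.0931). With arrays centred on their median 1 cytokine receptor and 1 interferon response gene rose, and with the block and covariate 2 cytokine receptors rose and 1 replication gene fell.

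Marker lists of tissue, red cells and group 2 innate lymphoid cells held 3 to 10 measured genes. None was called by camera with all 12 arrays after quantile normalization, with 1 probe set per gene. Fry, which does not compare a list with other genes, called each of them from DN2 to DN3 (fry adjusted p = 0.00116 to 0.0411). It also called some of them in the other comparisons. For thymic epithelium 2 of 10 rose and 0 fell from DN2 to DN3, where Epcam rose by 1.48 ± 0.31 (adjusted p = 0.00787), and 1 rose and 2 fell from DN3 to DN4 (camera adjusted p = 0.29 and 0.216). For fibroblasts the camera adjusted p was 0.14, 0.887 and 0.733 over the comparisons in the order given, for endothelium 0.195, 0.117 and 0.581, and for group 2 innate lymphoid cells 0.262, 0.541 and 0.43. For erythroid markers it was 0.0592, 0.534 and 0.148, and from DN2 to DN3 it was 0.0495, 0.0319 and 0.0491 without DN4 replicate 2, 3 or 4. It was also 0.0446 with arrays centred on their median and 0.0341 without between-array normalization, where the endothelium list passed from DN3 to DN4 (0.0227). Without the 3 arrays of lowest signal the thymic epithelium list passed from DN2 to DN3 (0.0384), and with the mean of all probe sets it passed from DN3 to DN4 (0.0291). The fibroblast list passed the threshold from DN2 to DN3 without DN2 replicate 3 (0.0354).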

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

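The percentile test of the MHC class II pattern was chosen before its result was seen, and its repeat without DN4 replicate 1 was chosen only after that result was seen. Of 330 sets of 4 arrays of a stage examined for the results named, 14 held an array far from the others, where chance gives about 1 in 20, or 16.5. The distances below therefore carry little weight by themselves.

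The mean log2 level of 4 MHC class II genes was 5.99 on DN4 replicate 1, against a mean of 7.71 on the other DN4 arrays, and H2-Aa was at 5.69 against 8.46. Over the stages the score was 7.02 ± 0.49 (SD, n = 4) in DN2, 6.09 ± 0.39 in DN3 and 7.28 ± 0.88 in DN4. DN3 was lower than DN2 by -0.93 and DN4 higher than DN3 by 1.19, each in 4 of 4 sorts (exact two-sided permutation p = 0.0571 and 0.114). If antigen-presenting cells among the sorted cells were a source, other B cell and dendritic cell markers may follow the score from array to array within stages. Their mean correlation was 0.39 over 16 markers, 12 of them positive and 2 held by another list too, at percentile 99.99 of 10000 random lists matched on level, which passed the bound set beforehand. Without DN4 replicate 1 it was 0.179, at percentile 91.7, which did not, so the relation rests on that array and the source cannot be told apart from a change in the stages themselves, which was not tested. The brightest of these markers were Cd79b and Irf8, at mean log2 levels of 7.27 and 7.17, and the lineage stain named in the labels held no B cell or dendritic cell marker.

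Other values far from the other arrays of their stage are given without an explanation. On DN2 replicate 1, Runx3 was at a log2 level of 10.60 (9.68 on the others), Arhgef10l at 4.71 (2.87) and Nfe2 at 9.48 (8.52). On DN2 replicate 2, Rrp9 was at 8.53 (7.88) and Cdkn2c at 8.87 (9.05). Pdlim4 was at 4.17 on DN2 replicate 3 (2.91) and Epcam at 6.26 on DN2 replicate 4 (7.75). On DN3 replicate 2, Syk was at 8.05 (7.65) and Rrp9 at 9.11 (8.92). Nolc1 was at 10.84 on DN4 replicate 3 (11.26), Slc16a1 at 11.88 on DN4 replicate 4 (11.62) and Sqle at 9.99 on DN4 replicate 2 (9.47).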

How the results depend on the processing

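Values without normalization, within pairs of sorts, without the 3 arrays of lowest signal and with the Gapdh covariate were chosen after seeing the data. The cause of a change was not tested, except that leaving out arrays leaves fewer arrays and other filters and probe set rules test other genes. Leaving out 1 array or the 3 of lowest signal also repeats the filter. A gene above it on only 4 arrays can then go untested once 1 of these is left out. Over the alternatives other than leaving out an array, named genes kept their side of the threshold in 2562 cases, lost the call in 165 and gained it in 13, and lists did so in 1554, 62 and 79. Without 1 array these were 1927, 10 and 3 for genes and 1160, 14 and 26 for lists. No called gene among these turned its direction, and no called list turned its camera direction, which is relative to other genes. The median of a called list could still turn, as given for ribosome biogenesis and cholesterol synthesis without between-array normalization. A difference that was not called could also turn. Cd44 from DN3 to DN4 was at -0.13, and at 0.41 without the 3 arrays of lowest signal. The block changed the calls of H2-Aa, H2-Ab1 and 3 lists from DN2 to DN3 or DN3 to DN4 as given with them, and no other call of a named gene or list. Counts of called list members that it moved by over 1.5 times stand with the lists. Those of called lists that the scaling, the 3 arrays or the covariate moved as much stand there or with the totals.

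Genes called in DN3 against DN2 (1257) numbered 2332 with the sort as a block, 604 without normalization, 256 and 434 in sorts 1 and 2 or 3 and 4 only, and 397 with the block and the Gapdh covariate. In DN4 against DN3 (1818) there were 3388 with the block, 1124 with no filter, 2733 with every probe set by itself, 2876 without normalization, 231 and 233 within the pairs of sorts, 905 without the 3 arrays of lowest signal, and 2739 with the block and covariate. In DN4 against DN2 (3864) there were 6546 with every probe set, 1900 and 2253 within the pairs of sorts, and 2392 without the 3 arrays. Other alternatives stayed within 1.5 times these counts, apart from leaving out DN3 replicate 2 in DN4 against DN3 (1129). Counts of genes that differed at least 2-fold moved by over 1.5 times in 12 cases. Folds of named genes called over all arrays moved by as much in 29 of 146 cases with the mean of all probe sets, smaller in each, and in 18 and 7 of 154 with an offset of 1 or a floor, larger in each.

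Genes highest in DN3 (107) numbered 237 with the replicate block, 60 with no filter, 13 and 21 within the pairs of sorts, and 43 with the block and covariate. Genes lowest in DN3 (45) numbered 161 with the block, 69 with arrays centred on their median, 18 with no filter, 2 without normalization, 3 and 5 within the pairs of sorts, and 22 without the 3 arrays. Lists called by camera in DN3 against DN2 (14) numbered 8 with the filter at the 75th percentile, 9 in sorts 1 and 2, 1 with an estimated correlation and 27 with fry, which does not compare a list with other genes. In DN4 against DN3 (8) there were 0 with an estimated correlation and 17 with fry, and in DN4 against DN2 (12) there were 1 and 27.

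Leaving out 1 array at a time gave 959 to 1258, 1129 to 1923 and 3210 to 3834 genes in the comparisons in that order, 65 to 106 peak and 24 to 44 trough genes, and 11 to 17, 7 to 10 and 11 to 12 lists. The Gapdh 3'/5' difference was -0.45 to -0.21, 0.02 to 0.19 and -0.33 to -0.09, and that of beta-actin -0.11 to -0.05, 0.03 to 0.11 and -0.05 to 0.03. Every probe set by itself and only the 8 arrays were not run for lists. Genes near the filter have signals close to the background of the array, which compresses their fold changes.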

Other observations

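The tests of Cpa3 and of the unscaled signal were chosen only after the results they bear on were seen. From DN2 to DN4, of 14 glycolysis genes 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.113), with Pfkp, a phosphofructokinase, up by 1.34 ± 0.15, Pgam1 by 0.94 ± 0.12 and Ldha by 0.55 ± 0.10 (SE, n = 4, limma adjusted p = 2.88e-05, 8.45e-05 and 0.00142, 4 of 4 sorts each). With arrays centred on their median 10 glycolysis genes rose and 1 fell, and without between-array normalization 3 rose and 3 fell. Camera called the glycolysis list in both settings (adjusted p = 0.0332 and 0.0348) and with the mean of all probe sets (0.0474). Of 11 nutrient transporters 4 rose and 1 fell over all genes and adjusted over the list alone (camera adjusted p = 0.409), at a median of 0.17 that was -0.22 without between-array normalization. Slc16a1, a lactate transporter, rose by 1.13 ± 0.12 and Slc1a4 by 1.14 ± 0.15 (adjusted p = 1.90e-05 and 1.21e-04). In the hypoxia list 3 of 14 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.483), at a median of 0.22 that was -0.20 without between-array normalization. In the heat shock list 3 of 19 rose and 3 fell, or 4 and 3 adjusted over the list alone and 6 and 5 with the sort as a block (camera adjusted p = 0.881).

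From DN2 to DN4, 3 of 18 migration and adhesion genes rose and 8 fell, or 4 and 9 adjusted over the list alone (camera adjusted p = 0.0714, or 0.0251 with arrays centred on their median). Cd44, whose product defined the gates, is a member of this list. Its fall adds to the counts and the list tests, here and between DN2 and DN3. The integrin gene Itgb2 rose by 1.73 ± 0.15, while Itga4 fell by 1.70 ± 0.13 (adjusted p = 5.50e-06 and 2.12e-06), or differed by -1.10 with the mean of its probe sets. Between DN2 and DN3 the list had 2 risen and 6 fallen, or 4 and 7 adjusted over the list alone and 4 and 6 with the sort as a block (camera adjusted p = 0.0635), and passed the threshold without DN4 replicate 2 (0.0495) or DN4 replicate 4 (0.0491). Centring on the median (0.045), no filter (0.0462) and no between-array normalization (0.00783) also brought it past the threshold. So did leaving out probe sets that can match several transcripts (0.0458).

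Cpa3 was highest in DN2. If mature mast cells in the DN2 gate were the source, their other markers may be higher there by at least 1 on the log2 scale. The median difference between DN2 and DN4 over 10 other mast cell markers was 0.24, with an interquartile half-range of 0.585, and 8 of them lay below the filter, where a low signal excludes nothing. The 2 that passed it, Hdc and Gata2, were at log2 levels of 5.28 and 5.34 in DN2, and below the filter level in DN4. They were higher in DN2 by 1.89 and 1.07, or by at least 0.59 and 0.65 against the filter level, which is under 1. Gata2 is also held by the progenitor regulator list. With so few markers above the filter, mast cells in the gate cannot be told apart from a change in the DN2 cells themselves, which was not tested.

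The DN4 arrays had a lower unscaled median signal than the DN3 arrays. If the brightness of hybridisation and scanning were the cause, spike-ins added after amplification may fall by as much. Relative to them the median transcript was lower by -0.24 in DN4 (exact two-sided permutation p = 0.0857), in 4 of 4 sorts, at -0.35 to -0.04 (exact two-sided sign-flip p = 0.125, the smallest that 4 pairs can give). Poly-A spike-ins, added before amplification, differed by -0.38 relative to the median transcript (exact two-sided permutation p = 0.714), and by -1.83 to 0.54 in the sorts. Poly-A spike-ins are amplified together with the transcripts, so their ratio could not show a lower yield of the amplification, whatever its value. Neither permutation test passed the threshold, and the sign-flip test could not with 4 pairs. Brightness and a lower yield of amplified RNA therefore cannot be told apart from a change in the cells.

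Other splits of the 8 arrays of a comparison into 4 and 4 were fitted. In each comparison 1 of 35 splits, the real one, gave as many called genes. Other splits mix the stages, so the stage difference adds to the residual spread and keeps their counts low by construction. The arrays are also paired by sort, and 8 splits that part as many pairs cannot give a share under 0.05. Chance is therefore not excluded by this test. The real counts were 1257, 1818 and 3864, and the highest other counts 0, 2 and 1, or 0, 1 and 0 among the 8 splits that part as many pairs of the same sort. The split of sorts 1 and 2 from sorts 3 and 4 gave 0 in each. For genes highest or lowest in DN3, 152 in all, 3 of 100 assignments of the 12 arrays to stages gave as many, the real one included. The other 2 gave 1165 and 1115, several times the real count, with the 4 DN4 arrays as the middle group. There a gene that sets DN4 apart is called at both steps in opposite directions, so these counts follow from the assignment. The share is therefore no test of the genes highest or lowest in DN3.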
